A study of Mus musculus with 6 samples.

How the data were processed

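Small RNA libraries from mouse spinal cords were compared, 3 labelled control and 3 labelled SCI (spinal cord injury). Per the labels' protocols, control mice had a laminectomy at the T10 level without cord injury. The SCI mice had in addition a moderate contusion at T10 from a 10 g weight dropped 20 mm. All were killed on day 2 after surgery, and about 1 cm of cord around T10 was taken. Per the labels' protocols, 3 µg of total RNA from each sample went into a small RNA library made with the NEBNext small RNA kit. The libraries are taken to come from separate mice. On that reading the p-values measure the spread between animals of a group, with everything that differed between their libraries included.

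The deposited table held 1482 rows, of which 1380 carried miRBase names and 102 were predicted miRNAs. For each library it gave whole-number read counts, which the authors deposited without normalization, and a column named TPM. The deposited TPM values equal CPM computed from the raw column totals, to within 2.74e-05, so they hold no term for length. Bowtie and the mm10 build are named in the submitters' processing notes, without a version. The miRBase release, the mismatch allowance, the treatment of reads that match several miRNAs or either strand, and the caller of predicted miRNAs are not given in the sources used here. Reads were assigned by the authors, so any sharing of reads between similar hairpins carries into every value. All 12 value columns were matched to samples through the sample descriptions. The columns of the SCI-labelled samples have names that begin with Normal, and those of the control-labelled samples have names that begin with Control.

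Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with a minimum count of 10, which left 614 rows holding 99.98% of the counts in each group. Library sizes were scaled by TMM. Differences came from edgeR's robust quasi-likelihood F test with group as the only term, and p-values were adjusted by Benjamini-Hochberg over the 614 rows at a threshold of 0.05. Levels are given as TMM-scaled CPM with the SD over 3 libraries. Log2 fold changes are SCI-labelled minus control-labelled, and their standard errors were taken as the size of the fold change over the square root of F.

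A signed list held miRNAs widely described as rising or falling after cord injury, or carried by infiltrating leukocytes. Its entry for a fall of miR-34a-5p was marked as uncertain. There were 19 further lists for cell types, pathways and genomic clusters. All these lists of miRNAs were fixed before the data were examined. Each was tested with camera from limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were tested, adjusted over 20 tests, and again with an estimated correlation and with fry. Arm usage was tested with edgeR's diffSpliceDGE on hairpins with both arms kept, adjusted over 179 hairpins. Library composition was compared by exact two-sided permutation tests over 30 measures; with 3 libraries against 3 the smallest p these can give is 0.1. The miRNAs named in the text follow a rule also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls past the test with non-overlapping libraries and a mean of at least 50 CPM, the 3 most abundant tested members of each list, the 5 most abundant miRNAs, and all tested members of the signed injury list. Predicted miRNAs were counted and not named. Other miRNAs that appear were chosen after their values were seen: the members of small counts, the examples of arm usage, and the miRNA families in the closing section.

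Hairpin positions were taken from GENCODE mouse release M21 on GRCm38, the assembly that mm10 denotes, by matching names, and 601 of the 614 tested rows matched a hairpin gene. No pair of libraries agreed within sampling noise. Alternatives covered the scaling (RLE, library total, upper quartile), the filter, DESeq2 1.42.0, limma voom with quality weights, limma on log2(TPM + 1) with pseudocounts of 0.1 and 10 as well, a test against a fold of 1.5, the replicate number as a block, leaving out each library, and leaving out miRNAs that could distort the totals. 2 alternatives were added after seeing the data: rows with near-equal counts taken as 1 row, and the skeletal muscle list left out.

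The steps were tested on simulated data drawn from the real means, library sizes and dispersions of this comparison. Known folds were given to 200 of the 614 rows, and 601 rows were kept by the filter. Of the changed rows that were kept, 62.8% of those changed 2-fold and 100% of those changed 4-fold were recovered. Changed rows lost to the filter are not in these shares. Of the calls, 3.68% were unchanged rows. All 4 shifted lists were called, and 0 of the 11 lists without a shifted member. Rows were drawn independently of each other, so list calls under correlation between members were not tested. Of 30 hairpins with a 4-fold arm shift among 175, 90% were recovered and 0 others were called. So at this depth a 2-fold change of a single miRNA could be missed. Library totals ran from 5568491 to 8889977 counts. Reads carry no molecular identifiers, so the counting error stated by a total understates the error of a library.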

Results

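The series was made to screen RNAs of the injured mouse spinal cord, and its small RNA libraries compare cords contused at T10 with cords that had only a laminectomy, 2 days after surgery. There were 3 libraries per group. Total counts were 6595364, 5568491 and 7360149 in the libraries labelled control 1, 2 and 3, and 7899382, 7100472 and 8889977 in those labelled SCI 1, 2 and 3. Between 1001 and 1086 rows had at least 1 count in a library. The most abundant miRNA was miR-21a-5p in control-labelled libraries 1 and 2, miR-9-5p in control-labelled library 3 and miR-10b-5p in each SCI-labelled library. The 10 most abundant rows held 52.8% ± 2.10 (SD, n = 3) of the counts in the control-labelled group and 57.6% ± 1.95 (SD, n = 3) in the SCI-labelled group.

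The 6 libraries separated by label. The leading principal component of log2 CPM carried 73.6% of the variance and parted the groups, with scores of -15.0 to -10.1 for control-labelled and 11.7 to 14.6 for SCI-labelled libraries. The next component carried 16.5% and set control-labelled library 3, at -12.5, apart from the others of its group, at 5.84 and 4.67. Across rows, Spearman's rho was 0.988 to 0.992 between SCI-labelled libraries and 0.987 between control-labelled libraries 1 and 2. It was 0.967 and 0.968 between these and library 3, and 0.925 to 0.947 across groups. Rows are not independent replicates.

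**Figure D1:**
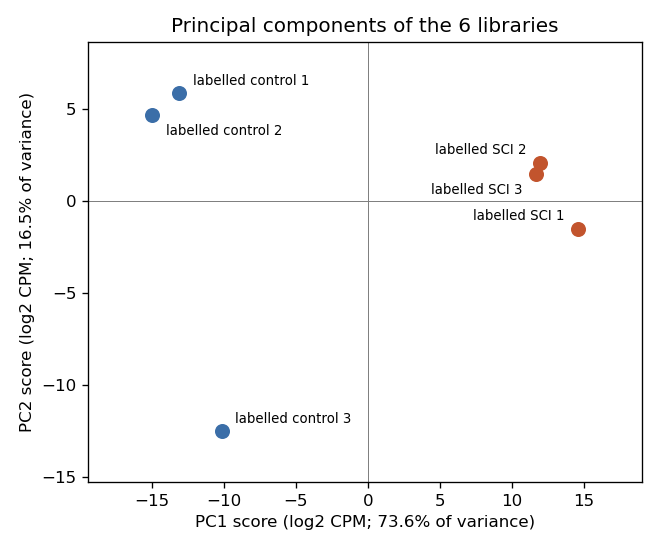
Scores of the 6 libraries on the first principal components of log2 CPM, with control-labelled libraries in blue and SCI-labelled libraries in orange. The horizontal axis (73.6% of variance) parts the groups, and control-labelled library 3 lies at -12.5 on the vertical axis (16.5%).

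The direction of the labels was checked first, with miRNAs known to respond to cord injury. These ran against the labels. All 9 tested miRNAs of the list expected to be higher after injury were lower in the SCI-labelled libraries and past the test, and in all 9 the libraries of the groups did not overlap. miR-21a-5p, the miRNA most widely reported to rise after tissue injury, was at 100083 ± 27262 CPM (SD, n = 3) in the control-labelled and 12003 ± 774 CPM (SD, n = 3) in the SCI-labelled libraries. That is 8.34-fold lower in the SCI-labelled group (log2 -3.06, SE 0.24; edgeR quasi-likelihood adjusted p = 7.02e-05). miR-223-3p, which is made by neutrophils and other myeloid cells, was at 114 ± 18.6 CPM and 8.45 ± 2.54 CPM (SD, n = 3 each), 13.5-fold lower. The leukocyte miRNA miR-142a-5p was 14.7-fold lower, miR-142a-3p 7.11-fold, miR-155-5p 4.69-fold, miR-221-3p 2.90-fold, miR-222-3p 2.01-fold and miR-146a-5p 1.82-fold. miR-21a-3p had 17, 32 and 54 counts in the control-labelled libraries and 0, 0 and 2 in the SCI-labelled ones.

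Of the 10 tested miRNAs of the list expected to be lower after injury, most of which are on the neuron or oligodendrocyte lists, 8 were higher in the SCI-labelled libraries and 3 of these passed the test. These were miR-128-3p (2.76-fold higher), miR-34a-5p (2.63-fold) and miR-129-5p (2.40-fold). The expected fall of miR-34a-5p was marked as uncertain when the list was fixed. The others did not pass it: miR-137-3p had a log2 change of 0.79, miR-138-5p 0.61, miR-338-3p 0.26, miR-129-2-3p 0.26, miR-219a-2-3p 0.07, miR-124-3p -0.52 and miR-219a-5p -0.55. In all, 12 of 19 members were past the test against the expected direction and 0 in it. The 2 members with the expected sign were past neither the adjusted nor the unadjusted edgeR test, and DESeq2 and limma voom called 0 of them. The signed list had a fry p of 0.00093 for a shift against expectation. miR-34a-5p lost its call without SCI-labelled library 1 (adjusted p = 0.0529) or 3 (0.0611), and miR-146a-5p without control-labelled library 1 (0.0555) or 2 (0.0619) or SCI-labelled library 1 (0.0937) or 3 (0.0901). Other calls against expectation were gained. Without control-labelled library 3, edgeR called miR-137-3p (log2 1.49, adjusted p = 0.00039), miR-138-5p (0.94, 0.0029) and miR-219a-5p (0.61, 0.0405) higher, and miR-124-3p stood at 0.23. miR-137-3p also passed with no filter (edgeR adjusted p = 0.0416) and with limma voom (0.0053). miR-138-5p also passed with the upper quartile (edgeR adjusted p = 0.0427) and with limma voom (0.0174). Because of this result the groups are called by their labels below, and each direction stated is that of the labels as deposited.

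**Figure D2:**
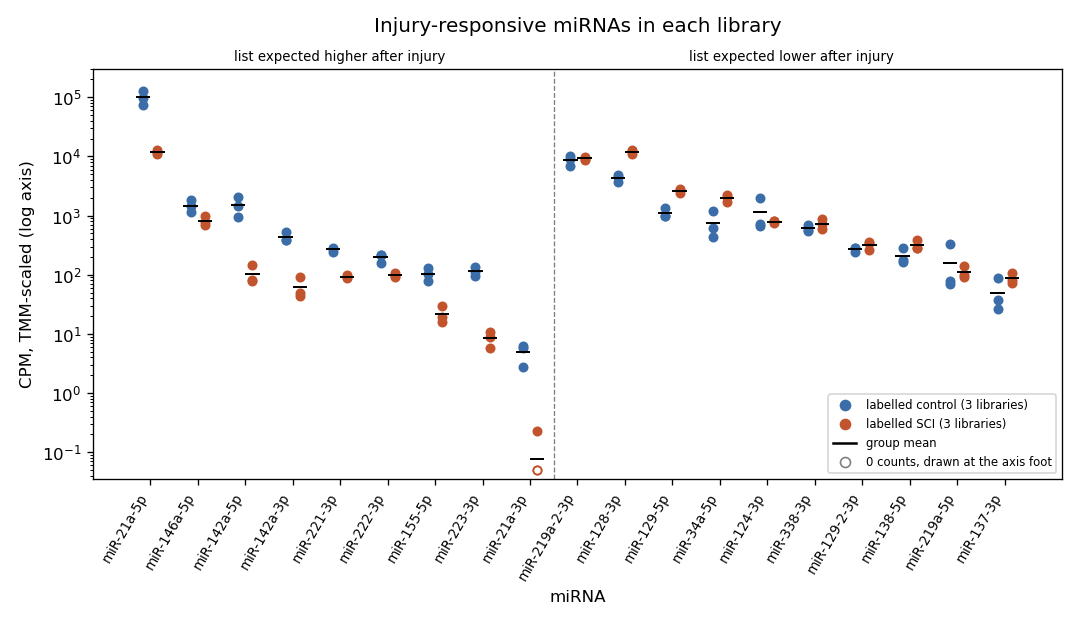
CPM (log axis) of the 19 tested injury-responsive miRNAs in each library, control-labelled in blue and SCI-labelled in orange, with bars at the group means of 3 libraries and open circles for 0 counts. All 9 miRNAs to the left of the dashed line lie lower in the SCI-labelled libraries, without overlap.

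Of the 614 rows tested, 242 differed between the groups: 100 were higher and 142 lower in the SCI-labelled libraries. The balance of these counts depended on the scaling, with 120 higher and 120 lower by the upper quartile and 75 and 144 by the library total. Of the called rows, 102 were lower by at least 2-fold and 47 by at least 4-fold, against 57 and 1 among the higher ones. The 1 row that was higher by over 4-fold, miR-292a-5p, had 1, 0 and 1 counts in the control-labelled and 15, 13 and 14 in the SCI-labelled libraries. In 240 of the 242 called rows the groups did not overlap. At an unadjusted p under 0.05 there were 285 rows. Of the 3 predicted rows tested, edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 and limma voom each called 1. The typical variation between libraries of a group was 26.7% (biological coefficient of variation). Counts of calls rested partly on single libraries: without control-labelled library 3 there were 152 higher and 179 lower, and without SCI-labelled library 3 there were 54 and 87. Without SCI-labelled library 1 there were 63 higher.

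The largest falls by the naming rule came from several lists. After miR-142a-5p and miR-223-3p, they were miR-19b-3p of the miR-17-92 cluster (12.2-fold lower), miR-486a-5p (11.9-fold), miR-486b-3p (11.8-fold) and miR-486a-3p (11.7-fold), miR-214-3p (10.8-fold), miR-144-5p (10.3-fold), miR-15b-5p (9.68-fold) and miR-21a-5p. The 3 miR-486 rows had near-equal counts and stand for 1 signal. The largest rises were smaller. They were miR-3059-5p (3.67-fold higher), miR-1298-5p (3.63-fold), miR-615-3p (3.51-fold), miR-495-3p (3.25-fold), miR-381-3p (3.00-fold), miR-29c-5p (2.95-fold), miR-132-5p (2.90-fold), miR-96-5p (2.84-fold), miR-128-3p and miR-135b-5p (2.72-fold). Adjusted p-values of these 20 miRNAs from edgeR ran from 4.82e-05 to 0.00453.

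Among the 5 most abundant miRNAs, miR-10b-5p was at 69517 ± 14384 CPM in the control-labelled and 156415 ± 21772 CPM in the SCI-labelled libraries (SD, n = 3 each), 2.25-fold higher. miR-9-5p, a miRNA of neural cells, was higher by 0.58 on the log2 scale (adjusted p = 0.0455 by edgeR) and miR-99a-5p 1.65-fold higher (0.0366). let-7i-5p had a log2 change of -0.32 and did not pass the test. The call of miR-9-5p was lost without any library but control-labelled library 3, with adjusted p-values up to 0.149 (without control-labelled library 2). The call of miR-9-5p was also lost with the library total only (0.131) and with limma on log2 TPM at pseudocounts of 1, 0.1 and 10 (0.0982, 0.0941 and 0.108) and over all rows (0.201). That of miR-99a-5p was lost without control-labelled library 2 (0.0791) or any SCI-labelled library (0.0571, 0.117 and 0.114 without 1, 2 and 3), and with limma on log2(TPM + 1) over all rows (0.0539).

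miRNAs of inflammation and white blood cells were lower in the SCI-labelled libraries. All 10 tested members of the inflammatory list were lower and past the test, 10 when adjusted over the list alone. The list's median log2 change was -1.96 (camera adjusted p = 6.54e-07). Besides the injury markers above, miR-146b-5p, a target and brake of NF-kB signalling, was 2.60-fold lower (adjusted p = 0.0131 by edgeR), a call lost without SCI-labelled library 2 (0.0555) or 3 (0.0689). Of 8 tested members of the leukocyte and microglia list, 6 were lower and 2 did not pass (adjusted over the list alone, 6 were lower), with a median of -2.53 (camera adjusted p = 5.08e-05). miR-342-3p, at 355 and 356 CPM, did not pass. With an estimated correlation the adjusted p was 0.134 for the inflammatory and 0.257 for the leukocyte list. 1 member, miR-155-5p, stands on both lists, and 6 members of the inflammatory, 4 of the leukocyte and 6 of the neuron list also belong to the signed injury list.

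Red blood cell miRNAs were also lower. All 6 tested members of the erythroid list were lower, 6 when adjusted over the list alone, with a median of -3.45 (camera adjusted p = 4.09e-06, and adjusted p = 0.257 with an estimated correlation). Of these 6, 3 are the miR-486 rows that stand for 1 signal. With near-equal rows taken as 1, 4 members were left, with a camera adjusted p of 0.000186. miR-451a, the main miRNA of red cells, was at 17204 ± 10185 CPM in the control-labelled and 2908 ± 1419 CPM in the SCI-labelled libraries (SD, n = 3 each), 5.92-fold lower. In control-labelled library 3 it was at 6411 CPM, against 26645 and 18555 CPM in the others of that group. The list took 3.22% ± 1.39 of counts in the control-labelled and 0.412% ± 0.187 in the SCI-labelled libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible).

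Clusters tied to cell division and mesenchyme followed the same direction. Of 16 tested members of the miR-17-92 cluster and its paralogs, 12 were lower and 4 did not pass, and 14 were lower when adjusted over the list alone. The median was -1.99 (camera adjusted p = 1.20e-11), and this was the only list called with an estimated correlation (adjusted p = 0.0411). miR-25-3p and miR-93-5p, which lie in the Mcm7 gene, were 4.13-fold and 3.67-fold lower, and miR-92a-3p was 3.26-fold lower. All 5 tested members of the fibroblast list, the miR-199 and miR-214 hairpins, were lower, 5 when adjusted over the list alone, with a median of -1.61 (camera adjusted p = 0.00304, and adjusted p = 0.316 with an estimated correlation). miR-199a-3p was at 1780 ± 479 CPM in the control-labelled and 582 ± 185 CPM in the SCI-labelled libraries (SD, n = 3 each). miR-199a-5p was 3.37-fold and miR-199b-5p 3.06-fold lower. The hypoxia miRNAs miR-210-3p and miR-210-5p were 2.55-fold and 4.98-fold lower, 2 of 2 when adjusted over the list alone, and this list was too short for a set test. Of 8 tested members of the epithelial and ependymal list, 5 were lower and 3 did not pass (adjusted over the list alone, 5 lower), among them miR-200c-3p (12.5-fold lower, at 2.60 CPM in the SCI-labelled libraries) and miR-200b-3p (4.83-fold). The list's median was -0.94, and it was called by fry (adjusted p = 0.00295) and not by camera (0.0937), except with no filter (0.00688), with the replicate block (0.0356) and without SCI-labelled library 2 (0.0487).

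Among miRNAs of neurons, more were higher than lower in the SCI-labelled libraries, but 9 of 17 did not pass the main edgeR test. DESeq2 called 9 of the 17 and limma voom 11, and 10 had an unadjusted edgeR p under 0.05. Of 17 tested members, 7 were higher, 1 lower and 9 did not pass, and adjusted over the list alone 8 were higher and 1 lower. The list's median log2 change was 0.61 (camera adjusted p = 0.00943, and adjusted p = 0.316 with an estimated correlation). miR-218-5p, a miRNA of motor neurons, was at 7503 ± 1557 CPM in the control-labelled and 20088 ± 2320 CPM in the SCI-labelled libraries (SD, n = 3 each), 2.68-fold higher. The member that was lower was miR-212-3p (log2 -0.91), and miR-7a-5p (0.44) did not pass. In control-labelled library 3 the list's median log2 ratio over control-labelled libraries 1 and 2 was 0.51, with members on both sides: miR-124-3p was at 2008 CPM against 660 and 725, and miR-128-3p at 3733 CPM against 4462 and 4854. Of the 3 tested members of the sensory neuron cluster, miR-96-5p was higher and miR-182-5p (0.39) and miR-183-5p (0.28) did not pass; adjusted over the list alone, 1 was higher (camera adjusted p = 0.222).

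In the imprinted Dlk1-Dio3 cluster on chromosome 12, more members were higher than lower. Of 42 tested members, 19 were higher, 2 lower and 21 did not pass, with the same 19 and 2 counts adjusted over the list alone. The median was 0.52 (camera adjusted p = 0.000338, and adjusted p = 0.0996 with an estimated correlation). miR-434-5p was 2.68-fold higher, miR-127-3p 1.70-fold and miR-381-3p 3.00-fold. The call of miR-127-3p was lost without SCI-labelled library 3 (adjusted p = 0.0689) and with limma on log2(TPM + 1) over all rows (0.0672). The 2 members that were lower were miR-494-3p (log2 -3.09) and miR-376b-3p (-1.05). The cluster took 4.27% ± 0.723 of counts in the control-labelled and 7.26% ± 0.756 in the SCI-labelled libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Of 7 tested members hosted by Hox gene clusters, which mark position along the body axis, 3 were higher and 4 did not pass (adjusted over the list alone, 3 higher). They were miR-10b-5p, miR-10a-5p (1.81-fold) and miR-615-3p. The median was 0.24, and the list was called by fry (adjusted p = 0.00929) and not by camera (0.149), except with no filter (0.0225). The call of miR-10a-5p was lost without control-labelled library 2 or any SCI-labelled library, with edgeR adjusted p-values of 0.0813, and of 0.0605, 0.126 and 0.0630 without SCI-labelled 1, 2 and 3.

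Other cell types showed little difference that passed the test. None of 7 tested oligodendrocyte members, 4 astrocyte members, 4 endothelial members or 9 let-7 members was past the test by edgeR, over all rows or adjusted over the list alone. At an unadjusted p under 0.05 there was 1 let-7 member and 0 of the other lists; DESeq2 called 0 members, and limma voom called 1 of let-7 and 0 of the others. miR-219a-2-3p was at 8765 ± 1644 and 9228 ± 536 CPM (SD, n = 3 each), miR-219b-5p had a log2 change of -0.02 and miR-338-5p -0.23. miR-29a-3p (-0.10), miR-29b-3p (0.34) and miR-29c-3p (-0.14) of the astrocyte list, miR-126a-3p (-0.26) and both miR-126a-5p and miR-126b-3p (-0.45), which share counts, of endothelium, and let-7f-5p (-0.49) and let-7g-5p (-0.11) did not pass. In smooth muscle and pericytes 1 of 4 members, miR-143-5p, was lower (log2 -0.90; 1 adjusted over the list alone), while miR-143-3p (0.05), miR-145a-5p (0.39) and miR-145a-3p (-0.29) did not pass. Camera adjusted p-values of these 5 lists were 0.843 to 0.958. Without control-labelled library 3 some members did pass the edgeR test: miR-29b-3p (log2 0.81, adjusted p = 0.00599), miR-126a-3p (-0.49, 0.0332), miR-145a-5p (0.59, 0.0375), let-7f-5p (-0.68, 0.00701) and let-7i-5p (-0.51, 0.0196), and miR-29c-3p and miR-219a-5p turned to higher (0.61 each, adjusted p = 0.0267 and 0.0405). For the oligodendrocyte, astrocyte and endothelial lists and for skeletal muscle, camera ranked the list upward although its median log2 change was below 0.

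Skeletal muscle miRNAs varied within the control-labelled group. miR-133a-3p was at 1581 CPM in control-labelled library 3 and at 129 and 171 CPM in libraries 1 and 2, against 353 ± 8.12 CPM (SD, n = 3) in the SCI-labelled group. miR-1a-3p, with which miR-1b-5p shares its counts, was at 35195 CPM in that library and at 8025 and 11622 CPM in the others of its group. Of 8 tested members, 1 was higher, miR-499-5p (log2 0.81), and 7 did not pass, while adjusted over the list alone 0 did (camera adjusted p = 0.895). Without control-labelled library 3, miR-133a-3p had a log2 change of 1.28 and passed the test (edgeR adjusted p = 0.00022). Of 9 members of the p53 list, 1 was higher (miR-34a-5p), 2 were lower (miR-34c-3p and miR-215-5p) and 6 did not pass, with the same counts adjusted over the list alone. miR-34c-5p (-0.24) and miR-192-5p (-0.27) were among those that did not. In the Sfmbt2 cluster, 2 of 16 members were higher, 5 lower and 9 did not pass, again with the same counts over the list alone. The 2 higher rows, miR-467a-5p and miR-467b-5p (2.67-fold), had equal counts, and miR-669c-5p (0.15) did not pass. Of the lower rows, miR-466b-3p (log2 -1.21) had counts near-equal to those of miR-466a-3p, another member of the list. Camera called neither list (adjusted p = 0.737 and 0.895).

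**Figure D3:**
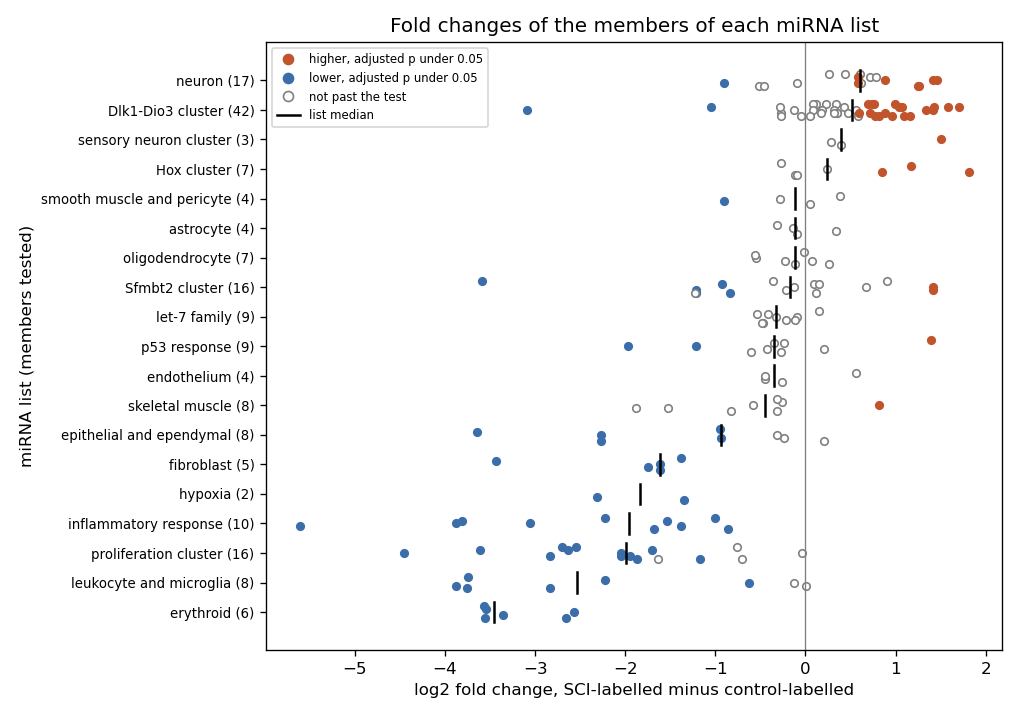
Log2 fold change, SCI-labelled minus control-labelled, of each tested member of the 19 lists, filled where the adjusted p was under 0.05 (orange higher, blue lower), with a bar at each list's median. The erythroid (-3.45), leukocyte (-2.53), proliferation (-1.99) and inflammatory (-1.96) medians lie furthest to the left, and neuron (0.61) and Dlk1-Dio3 (0.52) furthest to the right.

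With both parts of the signed injury list included, camera called 9 of 20 lists, 3 higher and 6 lower, fry called 11, and camera with an estimated correlation called 1. Other groupings of these 6 libraries gave up to 10 camera calls, so a camera call here is read only beside its count of members.

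The arms of a hairpin did not always move together. In 54 of 179 hairpins the ratio of the 5p to the 3p arm differed between the groups (edgeR adjusted p under the threshold), 29 toward the 5p arm and 25 toward the 3p arm in the SCI-labelled libraries. Of the 50 hairpins with both arms at 50 CPM or more, 20 passed. In 5 hairpins, with arms paired by name, the arms were called in opposite directions: miR-212, miR-335, miR-361, miR-376b and miR-467a. The miR-467a-5p and miR-467a-3p rows share counts with miR-467b-5p and miR-467d-3p, so they may stand for different sets of hairpins. Among the 54, miR-467d, miR-466b and miR-129b also had a 3p row near-equal to a row of another hairpin. miR-335-5p was lower (log2 -1.45, SE 0.22) and miR-335-3p higher (0.86, SE 0.20), and their log2 ratio went from between 1.48 and 1.65 in the control-labelled libraries to between -0.91 and -0.53 in the SCI-labelled ones. In miR-140, the 3p arm was at 7851 ± 2185 CPM in the control-labelled and 1888 ± 330 CPM in the SCI-labelled libraries (SD, n = 3 each), while the 5p arm had a log2 change of -0.21 and did not pass. The number of hairpins past the test was 29, 33 and 29 without SCI-labelled library 1, 2 and 3, 36 without control-labelled library 2 and 71 without control-labelled library 3.

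In the annotation (GENCODE M21, GRCm38), the hairpin of miR-21a lies on chromosome 11 from 86584067 to 86584158 on the minus strand, in a UTR exon of Vmp1. The hairpin of miR-223 lies on chromosome X from 96242817 to 96242926 in an exon of a noncoding transcript. That of miR-142a lies on chromosome 11 from 87756864 to 87756927 in an intron of Mir142hg, and that of miR-486a on chromosome 8 from 23142555 to 23142682 in an intron of Ank1. Of the hairpins that were higher, miR-10b lies on chromosome 2 from 74726070 to 74726137 in introns of Hoxd3 and Hoxd4, miR-615 on chromosome 15 from 103014910 to 103015001 in an intron of Hoxc5, and miR-1298 on chromosome X from 147064905 to 147065002 in an intron of Htr2c.

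The names of some rows are uncertain. Among rows with a mean of at least 50 counts, 16 pairs had counts within 0.1 of each other on the log2 scale in every library. In 10 of these pairs the hairpins lie on opposite strands of the same place, as with miR-1a-3p and miR-1b-5p, miR-126a-5p and miR-126b-3p, or miR-129-5p and miR-129b-3p. Of 26 pairs on opposite strands with a mean of at least 50 counts in either row, only these 10 were near-equal. Not all 26 could be, since some rows have no arm in their name. For example, miR-142b was set against both arms of miR-142a. Reads of such rows cannot be assigned to either strand here. Rows of the miR-466, miR-467 and miR-486 families share counts as well. With near-equal rows taken as 1 row, a choice made after seeing the data, 95 were higher and 138 lower.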

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

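The near-equal rows and the left-out muscle list were chosen after seeing the data; all other alternatives were fixed before. Of 80 named miRNAs, 49 passed the test, all 49 kept their direction in every setting that gave a value, and 40 of them passed in every one. No setting gave a shared call of opposite sign. Over the full-size alternatives other than the fold test, 69 to 123 miRNAs were higher and 98 to 159 lower in the SCI-labelled libraries, against 100 and 142. Members of the signed injury list past the test numbered 8 to 15, all against expectation; the 8 came with the leukocyte list left out, which holds 4 of them. Upper quartile scaling shifted the median log2 change by 0.12, and RLE by 0.03. The erythroid miR-451a lost its call only with no filter (adjusted p = 0.0906). A 2-fold change could be missed at this depth and spread.

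Tested against a fold of 1.5, 44 were higher and 85 lower, since a change must exceed that fold by more than its error. Calls were lost, at unchanged log2 changes, by miR-146a-5p (-0.86), miR-9-5p (0.58), miR-34a-5p (1.39), miR-10a-5p (0.85), miR-127-3p (0.77), miR-99a-5p (0.72) and miR-222-3p (-1.01). With an estimated correlation camera called 1 list. Leaving out 1 library at a time gave 54 to 152 higher, 87 to 179 lower, and 29 to 71 hairpins with changed arm usage. The highest values came without control-labelled library 3. Pairing by replicate number left no clear sign: deviations of same-numbered libraries correlated at -0.28, 0.21 and -0.19. Differently numbered libraries across the groups gave -0.26 to 0.37. With 3 libraries per group these values cannot exclude pairing. With the replicate block 78 were higher and 112 lower. Camera called the epithelial list with the block (adjusted p = 0.0356), with no filter (0.00688) and without SCI-labelled library 2 (0.0487), and the Hox list with no filter (0.0225). The list expected to be lower after injury (adjusted p = 0.0457) lost its camera call with the library total (0.0539), the erythroid and leukocyte lists left out (0.0555), a minimum mean CPM of 10 (0.0755), and without control-labelled library 1 (0.0983) or 2 (0.0773) or SCI-labelled library 1 (0.0621).

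Reversals concerned only miRNAs not past the main test, and their cause was not tested. Among the left-out libraries, control-labelled library 3 gave the most, 10 of 80 named miRNAs. Without it, 3 of the reversed miRNAs passed the edgeR test: miR-133a-3p (1.28, adjusted p = 0.00022), miR-29c-3p (0.61, 0.0267) and miR-219a-5p (0.61, 0.0405). Limma voom with quality weights also reversed 10. The log2 change of miR-342-3p was -0.079 with the library total only, -0.068 with limma voom, -0.094, -0.094 and -0.091 with limma at pseudocounts of 1, 0.1 and 10, -0.094 over all rows, -0.016 with the block and -0.0080 with near-equal rows taken as 1. miR-133a-3p was at 0.84 with voom, 0.030, 0.033 and 0.0065 with the pseudocounts, 0.030 over all rows and 0.21 with the block. miR-219b-5p was at 0.082 with the upper quartile, 0.030 with no filter, 0.035 with a minimum mean CPM of 10 and 0.0092 with the block. miR-29a-3p and miR-29c-3p were at 0.036 and 0.015 with the upper quartile and 0.17 and 0.37 with voom, and miR-29c-3p at 0.056 with the block. With voom, miR-219a-2-3p was at -0.014, miR-143-3p -0.077, miR-1a-3p and miR-1b-5p 0.31, miR-124-3p 0.0069 and miR-219a-5p 0.27.

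Leaving out 1 library, the log2 change ranged from -0.021 to 0.20 for miR-219a-2-3p, -0.11 to 0.19 for miR-219b-5p, -0.24 to 0.31 for miR-29a-3p, -0.41 to 0.61 for miR-29c-3p, -0.059 to 0.19 for miR-342-3p, -0.49 to 0.11 for miR-126a-3p, -0.14 to 0.37 for miR-143-3p, -0.59 to 0.62 for miR-1a-3p and miR-1b-5p, -1.30 to 1.28 for miR-133a-3p, -0.14 to 0.037 for let-7g-5p, -0.37 to 0.087 for miR-34c-5p, -0.023 to 0.78 for miR-183-5p, -0.77 to 0.23 for miR-124-3p and -0.90 to 0.61 for miR-219a-5p.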

Other observations

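Further groups of miRNAs, 10 in all, were formed after their values were seen, and no set test was run on them. Calls of single miRNAs in this part are those of the main edgeR test. All other tests in this part were chosen after the result was seen, and where they use lists, these were fixed earlier. Of 6 members of the miR-15/16 family, which restrain the cell cycle, 5 were lower in the SCI-labelled libraries and 1 did not pass: miR-16-5p was at 1888 ± 89.4 CPM in the control-labelled and 381 ± 13.2 CPM in the SCI-labelled libraries (SD, n = 3 each), 4.96-fold lower, and miR-15a-5p was 3.83-fold lower. Of 9 rows of the X-linked cluster of miR-322 and miR-503, 6 were lower and 3 did not pass (miR-322-5p counts in both groups), with miR-503-5p 9.56-fold and miR-542-3p 3.30-fold lower. Of miR-23, miR-27 and miR-24, 4 of 5 were lower, led by miR-23a-3p (3.62-fold). Among 5 miR-30 members only miR-30a-5p passed, 1.99-fold lower, while miR-30c-5p (log2 0.46) did not. Of the miR-181 family 1 of 4 was higher, of miR-26 1 of 2 was lower, and of miR-125 and miR-99 1 of 5 was higher, and their other members did not pass. Adjusted p-values of the miRNAs named here as lower ran from 7.02e-05 to 0.00167 in edgeR.

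In the other direction, 5 of 7 rows from hairpins in introns of Htr2c, a serotonin receptor gene on chromosome X, were higher in the SCI-labelled libraries. miR-1298-5p was 3.63-fold, miR-1264-5p 2.64-fold and miR-764-5p 2.60-fold higher, while miR-448-3p (log2 0.23) and miR-448-5p (0.37) did not pass. miR-204-5p, from an intron of Trpm3, was 2.45-fold higher (edgeR adjusted p = 0.00167). Of 4 rows of miR-132 and miR-212, whose 3p arms are on the neuron list, 2 were higher, 1 lower and 1 did not pass: miR-132-5p was 2.90-fold higher while miR-132-3p had a log2 change of -0.09 and did not pass.

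The first pattern is that miRNAs known to rise after injury were lower in the libraries labelled SCI. The tables argue against a single wrong label: 0 of the 6 libraries lay on the other group's side for most of the 9 injury-raised miRNAs. The counts alone cannot tell an exchange of the labels of both whole groups from a difference as labelled, since it would only reverse every sign. The signed injury list, fixed before the data were examined, bears on that sign, but its 9 injury-raised members are the pattern itself. Of the 10 miRNAs expected to fall, which are outside the pattern, 3 were called against expectation and 0 with it. The uncertain miR-34a-5p is among the 3. Without control-labelled library 3, miR-137-3p, miR-138-5p and miR-219a-5p were called against expectation as well. The columns of the SCI-labelled samples are named Normal. Blood carried into the control-labelled libraries could raise the erythroid and leukocyte miRNAs, and cannot be told apart here: in control-labelled library 3 the injury-raised miRNAs stood 0.93 log2 units above the erythroid list relative to the other libraries of the group, but that rests on 1 library. A biological difference as labelled, with these miRNAs lower after contusion than after laminectomy, stays open and untested.

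The second pattern is that control-labelled library 3 stood apart from the others of its group. Skeletal muscle carried along with the cord may account for its muscle miRNAs: 7 of the 8 tested members of that list, with miR-1a-3p and miR-1b-5p sharing reads, were highest in it among the 6 libraries, with a median log2 ratio of 2.78 over libraries 1 and 2. Muscle does not explain the rest, since 6 of 28 members of the neuron, oligodendrocyte and astrocyte lists, miR-124-3p and miR-219a-5p among them (the latter shares reads with another of the 6, miR-219b-3p), lay over 1 log2 unit above both. Another mix of cord cells as the whole cause would move both arms of a hairpin together. Across 50 hairpins the shifts of the 5p and 3p arms in this library correlated at -0.06 (SE 0.14), against 0.67 for the changes between the groups. That argues only weakly against this cause, since low values were not particular to library 3. Control-labelled libraries 1 and 2, compared in part with library 3, gave -0.16 and 0.21. SCI-labelled libraries 1, 2 and 3 gave 0.47, 0.22 and 0.56. A difference in library preparation stays open, with no batch given in the labels, and no biological explanation was tested.

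The third pattern is that pairs of rows carried near-equal counts. Counting without regard to strand may account for 10 of the 16 pairs, which lie on opposite strands of the same place. Only 10 of 26 such pairs with enough counts were near-equal, though (miR-126a-3p had 789989 counts and miR-126b-5p 5755). Some of the 26 could not be, such as miR-142b with miR-142a-5p, since miR-142b already had the counts of miR-142a-3p. Without the positions of mature miRNAs the other unequal pairs stay unexplained. Reads shared between near-identical copies cannot be the cause of those 10 near-equal pairs. They could account for the miR-466 and miR-467 pairs among the 5 pairs with hairpins that were not found at 1 place. The others of these 5 join miR-486b-3p with miR-486a-3p and miR-486a-5p. No hairpin gene matched miR-486b-3p by name, so its place is unknown here and either cause stays open for them. The last pair is the arms of miR-486a. No biological explanation was tested.

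With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For the number of higher miRNAs the real split gave 100 and the highest other 0, with 1 split as large, the real one. For lower miRNAs these were 142 and 0, with 1 split as large, for members of the signed injury list 12 and 0, with 1, and for hairpins with changed arm usage 54 and 0, with 1. For lists called by camera the real split gave 9 and the highest other 10, and 4 of the 10 splits gave at least 9. The splits with 10 put control-labelled library 3 with 2 SCI-labelled libraries. The 3 splits with control-labelled library 2 in that place gave 8, 7 and 4, and the cause was not tested.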
